A study of Homo sapiens with 12 samples.

How the data were processed

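Total RNA of MOLM14 acute myeloid leukemia cells carrying a doxycycline-inducible shRNA against RIP140 was sequenced in paired-end mode on an Illumina NovaSeq instrument, per the labels' protocols. The deposited values are whole-number counts per gene and library, not normalized. Per the submitters' processing notes, FastQC, STAR and HTSeq were used with the GRCh38 build. Versions, the annotation release and the strand setting are not given there. Without these a gene and an overlapping or antisense partner cannot be told apart, and genes with near-identical copies may share or lose reads. The deposited table held 61487 gene identifiers, 61474 of them paired with a symbol, and 23 empty columns; no column with values was left without a sample. Of the identifiers, 61369 were found in a table of gene names and 58312 in GENCODE release 29, which gave the GRCh38 coordinates.

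The 12 libraries were assigned from the labels to untreated, ATRA, DOX and combined groups, 3 each. Library totals, in units of 1e6 counts, ran from 2.69 to 19.36, a ratio of 7.21. Floors and counting intervals cover counting error only, while the intervals of NRIP1 come from the standard error implied by the quasi-likelihood F test. The fit used edgeR 4.0.16 in R 4.3.3: filterByExpr kept 16104 genes, TMM scaled the libraries. A single quasi-likelihood model of the 4 group means gave every contrast, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 9.54%. Contrasts were ATRA, DOX and combined against untreated, combined against ATRA and against DOX, the interaction (the ATRA effect with DOX minus that without), and the DOX effect averaged over both ATRA states. A fold against a group without counts is a lower bound from 3 counts over the group, and with 1 to 3 counts it is a ratio of counts with an exact 95% counting interval.

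Named genes follow a rule written, with the design and the gene lists, before the data were examined: NRIP1, and in each contrast the 8 largest increases and 8 largest decreases among called genes with an ordinary symbol, a mean of at least 2 CPM and, in comparisons of 1 group with another, no overlap between their libraries. Up to 4 members of a list with the smallest adjusted p may be named, and followed in the other contrasts. The 24 lists were retinoid response, mature myeloid, azurophil granule, myeloid transcription factor, HOX and stem cell, cell cycle, ribosome biogenesis, interferon, NF-kB, class I and class II antigen presentation, fatty acid oxidation, nuclear respiratory chain, mitochondrially encoded, integrated stress, p53 target, cholesterol synthesis, LXR and lipid, nuclear receptor coregulator and partner receptor, apoptosis, lymphoid, erythroid and megakaryocyte, fibroblast and epithelial, and replication histone genes. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a contrast, and with the correlation estimated as an alternative. Lists with fewer than 5 measured members are given as values. The size of the ATRA response was compared over genes called for the mean ATRA effect, with fry on the interaction signed by direction and a total least squares slope through the origin.

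The edgeR contrasts, camera for DOX against untreated and the response size were also run on simulated counts that held known changes and had the measured means, depths and dispersions; DESeq2 was not. For changes of 1.5-, 2- and 4-fold, edgeR recovered 55.2, 86.6 and 100% of changed genes for ATRA against untreated (15823 genes tested), 65.7, 79.1 and 98.5% for DOX against untreated (15815) and 56.7, 86.6 and 98.5% for combined against ATRA (15828). It recovered 50.7, 82.1 and 98.5% for combined against DOX (15818), 64.2, 83.6 and 100% for combined against untreated (15824), 32.8, 67.2 and 97.0% for the interaction (15802) and 82.1, 92.5 and 100% for the mean DOX effect (15837). Changes were put into 67, 67 and 66 genes, all with a mean of at least 2 CPM, so these shares hold for such genes only. Unchanged genes called by mistake numbered 5, 11, 12, 10, 12, 4 and 17 in the same order of contrasts. For DOX against untreated (15841 genes), camera on n = 12 libraries gave p = 9.49e-40 for a simulated list shifted 1.3-fold and p = 0.842 for an unshifted list. The response size was simulated after its value was seen. With simulated ATRA changes at 0.8 of their log2 size under DOX, the slope was 0.804 (15758 genes tested, 2062 in the test), and with equal changes 0.999 (15735 tested, 2049 in the test). On n = 12 simulated libraries, fry gave p = 2.52e-14 and p = 0.643 for these. All simulated genes were drawn independently of each other. Measured lists had estimated correlations from −0.00814 for apoptosis genes to 0.589 for replication histone genes. The simulations therefore cannot show how camera with a preset correlation, or fry, behaves where genes move together.

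Alternatives were DESeq2 size factors or library size in place of TMM, no filter or at least 1 CPM in 3 libraries, a replicate-number block, DESeq2 1.42.0, only the compared groups, counts thinned to the smallest library, each library left out in turn, genes of at least 10 CPM for the response size, and an estimated correlation. An adjusted p that DESeq2 left missing was kept missing. After the data were seen, 3 were added: untreated replicate 3 and DOX replicate 3 left out together, log2 CPM of the 2 mitochondrial ribosomal RNA genes as a model term, and each library's trend on transcript length and GC content removed, for which 97.8% of tested genes had both values.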

Results

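RNA was sequenced from MOLM14, a human acute myeloid leukemia cell line of monocytic character that carries a KMT2A fusion. The cells held an shRNA against RIP140, the nuclear receptor coregulator encoded by NRIP1, whose expression is switched on by doxycycline (DOX). The 12 libraries formed 4 groups of 3 biological replicates: untreated, all-trans retinoic acid (ATRA, 1 µM for 48 h), DOX (50 ng/mL), and ATRA with DOX, called the combined group here. Gene counts, in units of 1e6, summed to 10.37, 11.54 and 18.07 in the untreated libraries and to 15.49, 9.51 and 10.03 in the ATRA libraries. They summed to 12.23, 19.36 and 2.69 in the DOX libraries and to 16.07, 12.7 and 9.45 in the combined libraries, so DOX replicate 3 had the least depth. Errors of log2 fold changes are standard errors implied by the quasi-likelihood F test, that is, the log2 change over the square root of F. They can fall below counting error where a group held few counts, as for TGM2 with 7 untreated and 4 DOX counts. Errors of CPM (counts per 1e6 counts, TMM-scaled) are SD, and n = 3 per group throughout.

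The targeted gene, NRIP1 (chromosome 21, positions 14961235 to 15065936 of GRCh38), was lower in every library given DOX than in every library without it. Its level was 59.7, 58.9 and 53.3 CPM in the untreated libraries and 38.4, 41.1 and 51.9 CPM in the ATRA libraries. The DOX libraries held 19.2, 14.99 and 15.7 CPM and the combined libraries 15.9, 20.9 and 19.95 CPM. DOX left 29.3% of the untreated level (95% interval 24.1 to 35.6), and 43.0% of the level in ATRA alone when ATRA was present (35.7 to 51.7). The log2 changes were −1.77 ± 0.13 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.47e-07) and −1.22 ± 0.13 (adjusted p = 6.49e-06). ATRA alone lowered NRIP1 by −0.39 ± 0.12 (adjusted p = 0.0185), a call lost without untreated replicate 1 or 2 or ATRA replicate 1 or 2, with values between −0.37 and −0.29, and at equal depth (−0.33). Under DOX, NRIP1 did not differ measurably between cells with and without ATRA (0.16 ± 0.14, adjusted p = 0.481). The difference between both DOX effects was 0.55 ± 0.19 (adjusted p = 0.276), and passed the threshold only without DOX replicate 1 (0.70, adjusted p = 0.0352).

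**Figure D1:**
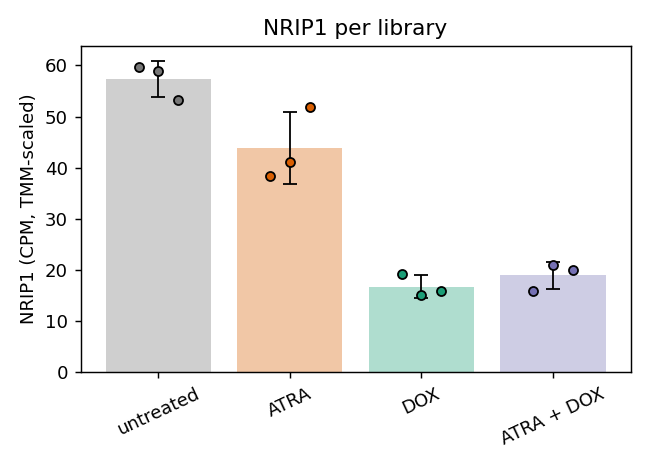
NRIP1 level in CPM for each library (points), with the group mean (bars) and SD (whiskers), 3 libraries per group. Means were 57.3 in untreated, 43.8 in ATRA, 16.6 in DOX and 18.9 CPM in combined libraries.

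The first comparison, ATRA against untreated cells, asked what the retinoid does while the shRNA is off. Genes with established retinoid links rose: TGM2, a transglutaminase long known as retinoid-induced, rose from 0.215 ± 0.197 to 306 ± 49.5 CPM (log2 change 10.69 ± 0.26). DHRS3, a retinaldehyde reductase, rose by 6.04 ± 0.16, CD38, an NAD-consuming surface enzyme, by 3.90 ± 0.11, and the retinoid-degrading CYP26B1 by 2.88 ± 0.13. PTGES, the prostaglandin E synthase, had no count in untreated cells and was at least 730-fold higher. NGFR, the low-affinity nerve growth factor receptor, was at least 157-fold higher and CCL2, a monocyte chemokine, at least 59.9-fold, each against a floor of 3 counts over the untreated group. MLXIPL, which encodes the glucose-responsive factor ChREBP, rose 215-fold (95% counting interval 59.0 to 1778) and SLAMF7, a leukocyte receptor, 103-fold (34.8 to 501). THBS1, encoding thrombospondin, rose by 7.75 ± 0.29 and RHBDL3, a rhomboid-family gene, by 7.45 ± 0.24. The calprotectin genes went the other way, S100A9 with −4.70 ± 0.26 and S100A8 with −3.82 ± 0.28. BCL2, the anti-apoptotic gene, fell from 128 ± 3.33 to 16.7 ± 1.18 CPM (−2.94 ± 0.11). CYP2W1, an orphan cytochrome (−4.22 ± 0.39), CSRP3, a LIM protein (−3.80 ± 0.44), RGS18, a G-protein regulator (−3.19 ± 0.39), NOG, a BMP antagonist (−2.91 ± 0.34), and TNFRSF19 (−2.62 ± 0.17) were also lower. The largest adjusted p among these genes was 6.74e-06 (edgeR quasi-likelihood). Of 20 measured retinoid response genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), and camera placed the list above other genes (adjusted p = 3.07e-15). The list's median, 1.42, does not depend on CCL2, its one gene without counts in untreated cells.

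Immune gene groups rose under ATRA. All 11 measured class II antigen presentation genes rose (11 adjusted over the list alone, median 3.82, camera adjusted p = 1.03e-11), from CIITA, the class II transactivator (1.05 ± 0.10), to HLA-DRA (6.35 ± 0.26) and HLA-DRB1 (6.02 ± 0.40). Class I genes rose at 13 of 15 (13 over the list alone, adjusted p = 2.03e-10), with PSMB9, an immunoproteasome subunit, at 1.33 ± 0.10. Of 40 interferon-stimulated genes, 31 rose (32 over the list alone, median 1.16, adjusted p = 3.22e-19), with IFI6 at 4.23 ± 0.26, OAS3 at 2.16 ± 0.17 and BST2 at 1.57 ± 0.09. NF-kB and inflammatory genes rose at 12 and fell at 3 of 23 (12 and 3 over the list alone, adjusted p = 0.00124), ICAM1 rising by 1.11 ± 0.11 and IL1RN, the interleukin-1 receptor antagonist, lower at −1.83 ± 0.22. Mature myeloid genes rose at 16 and fell at 4 of 21 (16 and 4 over the list alone, adjusted p = 4.87e-06), with NCF1, an oxidase subunit, at 3.93 ± 0.13 and ITGAM, encoding CD11b, at 1.38 ± 0.11. These lists and the retinoid list stayed past the threshold with an estimated correlation, at adjusted p between 0.000845 and 0.0403. HLA genes and NCF1 have near-identical relatives, so their separate counts are uncertain.

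Myeloid transcription factor genes rose at 13 and fell at 2 of 23 (13 and 4 over the list alone), with IRF1 at 1.98 ± 0.08 and IRF8 at 0.85 ± 0.09, camera adjusted p = 0.00367 and adjusted p = 0.301 with an estimated correlation. Azurophil granule genes rose at 8 and fell at 4 of 14 (8 and 4 over the list alone), SRGN at 2.29 ± 0.14 and SERPINB1 at 1.53 ± 0.09, adjusted p = 0.0297 and adjusted p = 0.382 with an estimated correlation. Apoptosis genes rose at 15 and fell at 2 of 27 (16 and 2 over the list alone, adjusted p = 0.000332), with BAK1 at 0.75 ± 0.08. Among 21 p53 targets 11 rose and 1 fell (12 and 2 over the list alone, adjusted p = 0.000332), including TP53I3 at 3.41 ± 0.12, BTG2 at 2.14 ± 0.13 and the cell cycle inhibitor CDKN1A at 0.66 ± 0.09. HOX, KMT2A-target and stem cell genes fell at 10 and rose at 3 of 27 (13 and 3 over the list alone, adjusted p = 0.00615), PBX3 falling (−0.54 ± 0.08) while the receptor gene KIT rose (2.95 ± 0.41). These last 3 lists held with an estimated correlation, at adjusted p between 0.0169 and 0.0348. Cell cycle genes fell at 21 of 41 (25 over the list alone, adjusted p = 1.09e-08), with UHRF1 at −0.79 ± 0.08 and E2F2 at −0.85 ± 0.12. Ribosome biogenesis genes fell at 10 of 30 (10 over the list alone, adjusted p = 0.000248), with FBL at −0.50 ± 0.10. Both lists lost the call, at adjusted p = 0.231 and adjusted p = 0.232 with an estimated correlation.

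Fatty acid oxidation genes rose at 10 and fell at 1 of 23 (10 and 1 over the list alone, camera adjusted p = 0.00487), with the carnitine carrier SLC25A20 at 1.08 ± 0.13. Nuclear respiratory chain genes rose at 9 of 42 (8 over the list alone, adjusted p = 0.00322, but adjusted p = 0.479 with an estimated correlation and 0.0810 with the mitochondrial ribosomal RNA term described below). The 13 mitochondrially encoded genes had 2 higher (0 over the list alone) and no list call (adjusted p = 0.0696). Cholesterol synthesis genes split into 4 higher and 5 lower of 22 (4 and 6 over the list alone, adjusted p = 0.360), SQLE rising by 0.71 ± 0.08 and LSS falling (−0.62 ± 0.08). LXR and lipid handling genes split into 5 higher and 2 lower of 14 (7 and 3 over the list alone, adjusted p = 0.384), PLTP rising by 1.41 ± 0.15. Integrated stress response genes split into 5 higher and 11 lower of 26 (7 and 12 over the list alone, adjusted p = 0.146), with a median of −0.30 and a camera direction downward against a mean of 0.04. Its members went apart, GDF15 rising by 5.12 ± 0.39 and SLC7A11, the cystine transporter, falling (−1.36 ± 0.17). Nuclear receptor coregulators and partner receptors other than NRIP1 had 1 higher and 4 lower of 25 (1 and 4 over the list alone, adjusted p = 0.119), with the retinoid X receptor gene RXRA at −1.17 ± 0.08. Replication-dependent histone genes fell at 7 and rose at 1 of 10 (8 and 2 over the list alone), with adjusted p = 0.0131, adjusted p = 0.382 with an estimated correlation, and adjusted p = 0.0621 without untreated replicate 3. Markers of other cells gave little: lymphoid genes fell at 3 of 6 (4 over the list alone, adjusted p = 0.00932, adjusted p = 0.111 with an estimated correlation). Of 4 erythroid and megakaryocyte genes 1 rose (1 over the list alone). Among 3 fibroblast and epithelial genes PECAM1 rose and KRT18 fell (1 and 1 over the list alone).

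Across all genes, ATRA called 4652 of 16104 tested (2529 higher, 2123 lower), of which 1365 changed by at least 1 on the log2 scale (783 higher, 582 lower). At the depth of the smallest library the count was 2656.

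The second comparison, DOX against untreated cells, asked what shRNA induction does without ATRA. SLITRK5, a neuronal-type membrane protein gene (chromosome 13, positions 87672615 to 87696272), fell from 116 ± 5.67 to 35.4 ± 5.54 CPM, a log2 change of −1.70 ± 0.11 (edgeR quasi-likelihood, adjusted p = 6.63e-09), about as far as NRIP1 itself (−1.77 ± 0.13). DHRS9, a retinol dehydrogenase, rose from 20.8 ± 0.818 to 58.2 ± 6.62 CPM (1.48 ± 0.12, adjusted p = 3.24e-07). CD52, a lymphocyte and monocyte surface antigen, rose from 2.75 ± 0.496 to 10.6 ± 2.29 CPM (1.85 ± 0.23, adjusted p = 0.000125). CCDC152, which overlaps the selenoprotein gene SELENOP on the opposite strand and cannot be counted apart from it without strand, rose by 1.44 ± 0.20. The chemokine receptor gene CXCR3 rose by 1.62 ± 0.30 and HLA-DQB1 by 1.40 ± 0.31. Scavenger receptor gene SCARF1 (1.48 ± 0.41), spliceosomal RNU4-2 (1.43 ± 0.45) and THBS1 (2.33 ± 0.61, from 6 to 26 counts) were also called higher. The histone genes H2BC14 (−1.77 ± 0.33) and H2BC13 (−1.59 ± 0.35), the transporter gene SLC16A4 (−1.70 ± 0.35), INSYN2B (−1.76 ± 0.42), SPDYE5 (−1.60 ± 0.41), which has near-identical copies, and SCART1 (−1.58 ± 0.28) were called lower.

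Nuclear respiratory chain genes rose at 25 of 42 under DOX (29 higher and 1 lower adjusted over the list alone, median 0.39, camera adjusted p = 2.34e-12), with NDUFA6 at 0.54 ± 0.09 and NDUFS4 at 0.75 ± 0.14, and adjusted p = 0.206 with an estimated correlation. Azurophil granule genes rose at 8 of 14 (11 over the list alone, adjusted p = 4.88e-07), including MPO, myeloperoxidase, at 0.69 ± 0.14 and the protease gene PRTN3 at 0.70 ± 0.13, and adjusted p = 0.130 with an estimated correlation. Histone genes of the replication list fell at 8 of 10 (9 over the list alone, median −1.09, adjusted p = 2.31e-08), H2BC21 by −1.45 ± 0.20, and adjusted p = 0.130 with an estimated correlation. That list was written beforehand as a sign of how RNA was selected, and whether selection differed between libraries was not tested. Of 21 p53 targets 6 rose (8 over the list alone, adjusted p = 0.000286), led by CDKN1A at 0.83 ± 0.09 (adjusted p = 2.7e-05), the only list here past the threshold with an estimated correlation (adjusted p = 0.0481). Class I antigen genes rose at 7 of 15 (7 over the list alone, adjusted p = 0.00168, adjusted p = 0.130 with an estimated correlation), PSMB9 by 0.66 ± 0.10. Fatty acid oxidation genes, several of which RIP140 is known to repress in metabolic tissues, rose at 4 of 23 (5 over the list alone, adjusted p = 0.00429, adjusted p = 0.0981 with an estimated correlation), ACAA1 by 0.38 ± 0.09. Retinoid response genes rose at 5 of 20 (5 over the list alone, adjusted p = 0.0279, adjusted p = 0.130 with an estimated correlation), including IRF1 at 0.49 ± 0.08 and CD38 at 0.57 ± 0.12. The list call was lost without untreated replicate 3 or DOX replicate 1. Camera also passed cell cycle genes (3 of 41 lower, adjusted p = 0.0182) and interferon genes (4 of 40 higher, adjusted p = 0.0279). It passed NF-kB genes (3 higher and 1 lower of 23, adjusted p = 0.0279) and ribosome biogenesis genes (2 higher and 1 lower of 30, adjusted p = 0.0412). With an estimated correlation these lay between 0.130 and 0.592, and each lost its call without at least 1 library. In the list of coregulators and partner receptors, LCOR, which like NRIP1 binds ligand-activated receptors as a corepressor, was lower (−1.27 ± 0.18, adjusted p = 0.00032), and 4 of 25 fell (4 over the list alone, list adjusted p = 0.0937).

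The share of counts on both mitochondrial ribosomal RNA genes moved with DOX and within groups: 2.54, 2.85 and 4.60% in untreated, 2.09, 2.74 and 2.64% in ATRA, 2.18, 1.02 and 1.296% in DOX, and 1.98, 2.02 and 1.23% in combined libraries. DOX called 2446 genes (1302 higher, 1144 lower), 387 of them by at least 1 on the log2 scale (69 higher, 318 lower). The count was 1573 with these groups fitted alone and 1197 at equal depth. It was 731 without untreated replicate 3, 4326, 659 and 1462 without DOX replicate 1, 2 and 3 in turn, 169 without untreated replicate 3 and DOX replicate 3 together, and 77 with mitochondrial ribosomal RNA as a model term. With that term or without that pair, the calls of H2BC14, H2BC13, SLC16A4, SPDYE5, SCARF1 and RNU4-2 were lost. The term also ended the call of CXCR3, whose change stayed at 1.68, and those of SCART1 (−0.79 with it) and HLA-DQB1 (0.80), and the sign of INSYN2B turned to 0.0163. Among list members the term ended the calls of NDUFA6 (0.36 with it), NDUFS4 (0.33), H2BC21 (−0.83), LCOR (−0.55), PSMB9 (0.49), ACAA1 (0.30), IRF1 (0.41) and CD38 (0.71). MPO, PRTN3, ACAA1 and CD38 were not called without the pair, and ACAA1 also not without DOX replicate 2 or at equal depth. SPDYE5 and INSYN2B were also not called without untreated replicate 3 or DOX replicate 2, and SCARF1 not without untreated replicate 2 or 3. HLA-DQB1 was not called without DOX replicate 2, RNU4-2 without any 1 untreated replicate or DOX replicate 2, and THBS1 without DOX replicate 1 or the pair. RNU4-2 was also lost with DESeq2, with library size alone and at equal depth, HLA-DQB1 at equal depth, INSYN2B without the pair and SCARF1 with these groups fitted alone. NRIP1, SLITRK5, DHRS9, CD52, CCDC152 and CDKN1A passed with the term and without the pair. The histone list's median went from −1.09 to −0.44 with the term and that of the respiratory chain from 0.39 to 0.12.

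**Figure D2:**
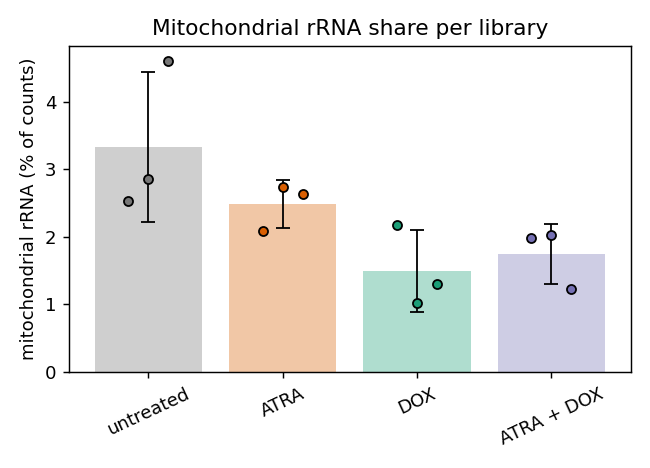
Share of each library's counts on the mitochondrial ribosomal RNA genes, in percent (points), with group mean (bars) and SD (whiskers), 3 libraries per group. The shares ran from 1.02% in DOX replicate 2 to 4.60% in untreated replicate 3.

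The third comparison, the combined group against ATRA alone, asked what shRNA induction does in cells exposed to ATRA. Class II antigen presentation genes were lower: 10 of 11 fell (10 over the list alone, median −1.58), HLA-DRA from 45.5 ± 2.65 to 11.3 ± 1.13 CPM (−2.005 ± 0.17, edgeR quasi-likelihood adjusted p = 9.94e-07), HLA-DPA1 by −2.07 ± 0.31, HLA-DRB1 by −1.80 ± 0.25, and CD74, the invariant chain, by −0.92 ± 0.11. Camera gave adjusted p = 7.44e-11 for the list and adjusted p = 0.194 with an estimated correlation. CD209, the dendritic cell lectin gene for DC-SIGN, fell from 124 ± 11.6 to 37.3 ± 9.41 CPM (−1.73 ± 0.16). ADAM28, a membrane metalloprotease gene, fell by −2.03 ± 0.22, NGFR by −2.09 ± 0.25 and SLITRK5 by −1.85 ± 0.10. IGIP was also lower (−1.75 ± 0.33), a call lost at equal depth. PTGES, already induced by ATRA, rose further from 54.6 ± 1.04 to 161 ± 39.9 CPM (1.56 ± 0.14, adjusted p = 2.23e-06). S100A9 was higher at 4.23 ± 0.947 against 0.911 ± 0.271 CPM (2.18 ± 0.31). GBP5, an interferon-inducible GTPase gene, rose by 2.10 ± 0.21, the protease inhibitor gene SLPI by 1.80 ± 0.25, and CD52 by 1.80 ± 0.27. The immediate-early gene IER3 rose by 2.03 ± 0.39, the pseudokinase gene TRIB1 by 1.75 ± 0.26 and TCF23 by 1.67 ± 0.32.

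Among retinoid genes in this comparison, RARB, the retinoic acid receptor beta gene, rose by 1.52 ± 0.29, DHRS9 by 0.77 ± 0.11, and CYP26B1 fell by −0.59 ± 0.11, with 2 higher and 1 lower of 20 (2 and 1 over the list alone, camera adjusted p = 0.703). Mature myeloid genes split into 2 higher and 4 lower of 21 (3 and 7 over the list alone), the scavenger receptor gene CD36 falling by −0.69 ± 0.11 and FCGR2B, whose reads FCGR2C can share, by −1.42 ± 0.18. That list's adjusted p of 0.0404 was lost without ATRA replicate 1 or 3 or combined replicate 1 or 2, and was adjusted p = 0.499 with an estimated correlation. Mitochondrially encoded genes fell at 5 of 13 (11 over the list alone, adjusted p = 6.4e-08, adjusted p = 0.312 with an estimated correlation), with MT-ND4 at −0.80 ± 0.17, not called without ATRA replicate 3 or combined replicate 2 or 3, and the mitochondrial ribosomal RNA share was 1.98, 2.02 and 1.23% against 2.09, 2.74 and 2.64%. LXR and lipid genes rose at 2 of 14 (2 over the list alone, adjusted p = 0.00838, adjusted p = 0.312 with an estimated correlation), SCD by 0.43 ± 0.09 and SREBF1 by 0.47 ± 0.12. SCD was not called without ATRA replicate 2 or combined replicate 2, and SREBF1 not without any 1 ATRA replicate or combined replicate 2 or 3, nor with the mitochondrial term. MPO rose by 1.13 ± 0.14 (adjusted p = 4.2e-05) while its list of 14 had 1 higher and 1 lower. LCOR was again lower (−0.99 ± 0.17) and NCOA7, a coactivator gene, higher (0.71 ± 0.12). Ribosome biogenesis genes leaned upward as a list (median 0.15, adjusted p = 2.93e-05, adjusted p = 0.328 with an estimated correlation), with 0 of 30 called by edgeR (0 over the list alone, 7 at unadjusted p under 0.05, all higher) and 0 by DESeq2.

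In total 713 genes were called in this comparison (304 higher, 409 lower), 129 of them by at least 1 on the log2 scale (44 higher, 85 lower). The count was 363, 411 and 264 without ATRA replicates 1, 2 and 3 in turn, 329 and 346 without combined replicates 2 and 3, and 415 at equal depth.

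Another comparison, the combined group against DOX alone, asked how the cells respond to ATRA once the shRNA is on. Of the retinoid genes, TGM2 rose by 11.07 ± 0.30, DHRS3 by 6.08 ± 0.17, CD38 by 3.13 ± 0.11 and RARB by 2.80 ± 0.35. PTGES was 2581-fold higher (95% counting interval 714 to 21320), MLXIPL 276-fold (49.2 to 10944) and CCL2 167-fold (29.7 to 6642), from 2, 1 and 1 counts in the DOX group, and NGFR at least 29.6-fold from 0 counts. RHBDL3 (6.55 ± 0.28) and GBP4, another interferon-inducible GTPase gene (6.50 ± 0.40), rose as well. Lower were CSRP3 (−3.99 ± 0.37), RGS18 (−3.44 ± 0.40), S100A8 (−3.24 ± 0.24), CYP2W1 (−3.20 ± 0.40), S100A9 (−2.79 ± 0.20), the retinaldehyde dehydrogenase gene ALDH1A3 (−2.61 ± 0.21), TNFRSF19 (−2.17 ± 0.17), the cannabinoid receptor gene CNR2 (−2.14 ± 0.24) and BCL2 (−2.12 ± 0.10). Retinoid response genes rose at 13 and fell at 2 of 20 (15 and 2 over the list alone, camera adjusted p = 5.65e-16) and interferon genes rose at 32 of 40 (33 over the list alone, adjusted p = 3.04e-21, adjusted p = 0.0560 with an estimated correlation). Class II genes rose at 7 of 11 (8 over the list alone, adjusted p = 1.3e-05, adjusted p = 0.122 with an estimated correlation) and class I genes at 10 of 15 (11 over the list alone, adjusted p = 1.01e-08, adjusted p = 0.0120 with an estimated correlation). By edgeR 3054 genes were called (1727 higher, 1327 lower), 830 by at least 1 on the log2 scale (576 higher, 254 lower), and 1891 at equal depth.

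The last paired comparison set the combined group against untreated cells. PTGES was at least 2068-fold, CCL2 at least 67.0-fold and NGFR at least 35.6-fold higher, TGM2 rose by 10.56 ± 0.27, THBS1 by 8.21 ± 0.28, GBP4 by 6.45 ± 0.37 and RHBDL3 by 6.40 ± 0.25, and MLXIPL was 166-fold higher (45.6 to 1377). CYP2W1 (−3.92 ± 0.37), RGS18 (−3.32 ± 0.39), CSRP3 (−2.89 ± 0.38), the metalloprotease gene ADAMTS14 (−2.71 ± 0.34), BCL2 (−2.57 ± 0.10), S100A8 (−2.56 ± 0.24), TNFRSF19 (−2.55 ± 0.17) and S100A9 (−2.52 ± 0.20) were lower. Apoptosis genes rose at 18 and fell at 2 of 27 (20 and 2 over the list alone, camera adjusted p = 9.6e-05, adjusted p = 0.0121 with an estimated correlation). By edgeR 6123 genes were called (3149 higher, 2974 lower), 1749 by at least 1 on the log2 scale (783 higher, 966 lower). The count was 3408 at equal depth and 3363 with the mitochondrial ribosomal RNA term.

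The interaction asked whether the ATRA effect differs with and without DOX, that is, with doxycycline and the shRNA together. Class II genes stood out, with a list median difference of −1.81 (4 of 11 lower, 7 over the list alone, camera adjusted p = 5.62e-11, adjusted p = 0.0629 with an estimated correlation). ATRA raised HLA-DRA by 6.35 ± 0.26 without and 3.68 ± 0.29 with DOX, HLA-DQB1 by 3.82 ± 0.25 and 1.19 ± 0.24, and CD74 by 1.49 ± 0.11 and 0.34 ± 0.11. It raised CIITA by 1.05 ± 0.10 without DOX against a value of 0.29 ± 0.10 that did not pass the test with it. Other genes that ATRA induced rose less with DOX, among them the receptor gene CCR2 (3.44 ± 0.15 against 2.25 ± 0.16) and the surface enzyme gene CD38 (3.90 ± 0.11 against 3.13 ± 0.11). So did FGL2, a fibrinogen-like gene (3.02 ± 0.16 against 1.72 ± 0.18), MS4A6A (2.62 ± 0.15 against 1.46 ± 0.15) and the sulfotransferase gene CHST2 (2.004 ± 0.16 against 0.79 ± 0.17). PTAFR, the platelet-activating factor receptor gene, rose by 1.63 ± 0.18 without DOX, against 0.06 ± 0.17 with it. In some genes the level before ATRA had moved too. PTAFR started at 14.4 CPM with DOX against 6.35 CPM without, and ATRA brought it to 14.7 against 19.8 CPM. CD38 started at 20.3 against 13.9 CPM and reached 180 against 207 CPM. HLA-DQB1 started at 2.68 against 1.09 CPM and reached 6.93 against 16.1 CPM. CCR2 started at near levels (11.3 against 9.93 CPM). HLA-DRA started at 0.582 ± 0.749 against 0.552 ± 0.124 CPM, from 30 and 22 counts, too few to show equal starts. Its difference of −2.67 between the ATRA effects was larger than the −2.005 between the groups given ATRA, so the fit placed part of it before ATRA. The repressed genes S100A9 (−4.70 ± 0.26 against −2.79 ± 0.20) and BCL2 (−2.94 ± 0.11 against −2.12 ± 0.10) fell less with DOX on the log2 scale. So did BCL11A, a transcriptional repressor gene (−2.28 ± 0.11 against −1.55 ± 0.11). BCL11A started lower with DOX (70.6 against 112 CPM) and reached 24.09 against 23.05 CPM. Its difference thus lay mostly in the level before ATRA. BCL2 started at 92.5 against 128 CPM and reached 21.5 against 16.7 CPM, so both levels had moved. S100A9 did not start lower with DOX, and reached 4.23 against 0.911 CPM. WNT6 (difference 0.93 ± 0.17) and INAVA (0.75 ± 0.15) rose under ATRA only in the test with DOX, and their differences passed too. RARB, whose ATRA effect was 0.65 ± 0.34 without and 2.80 ± 0.35 with DOX, had a difference of 2.15 ± 0.50 that missed the threshold (adjusted p = 0.075).

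**Figure D3:**
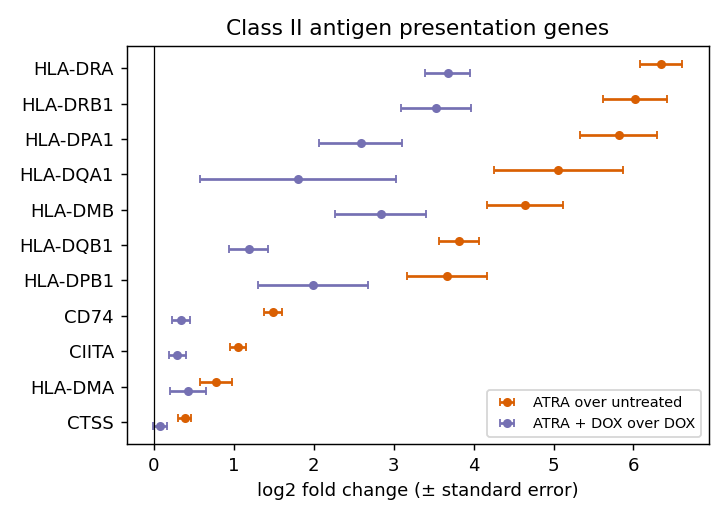
Log2 fold change of the 11 measured class II genes under ATRA without DOX and with DOX, with standard errors. HLA-DRA lay at 6.35 and 3.68, CD74 at 1.49 and 0.34, and each of the 11 genes had the lower value with DOX.

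By edgeR 43 genes had an interaction (7 higher, 36 lower; 14 of at least 1 on the log2 scale, 1 higher and 13 lower). Of these, 35 were induced by ATRA without DOX and had a lower log2 change with it, 5 were repressed and less so with DOX, and 3 were not called without DOX. That sorting uses libraries that also enter the interaction, and it does not tell a moved level before ATRA from a moved level with ATRA. The p53 targets leaned lower (median −0.28, camera adjusted p = 9.16e-08, adjusted p = 0.0058 with an estimated correlation), with BTG2 at −0.95 ± 0.19 and 1 of 21 called (6 over the list alone). Over the 5905 genes with a mean ATRA effect, chosen without regard to DOX, the change with DOX was a median of −0.0971 smaller on the log2 scale. In total 3844 genes (65.1%) had a smaller change with DOX when signed by the direction of the mean effect, which includes any that turned the other way (fry on the signed difference, n = 12 libraries, p = 0.00238). The slope of one response on the other, without a test, was 0.815, and 0.897 without DOX replicate 1. Induced genes had a median of −0.126 (3091 genes, fry p = 0.000708, n = 12 libraries) and repressed genes −0.0688 (2814 genes, p = 0.0434). Without DOX replicate 1 these became −0.0563 and 0.0082, and the median of all genes −0.0196 (fry, n = 11 libraries, p = 0.268). The repressed genes also missed the threshold without untreated replicate 3, DOX replicate 2 or 3, or combined replicate 1 or 2. Further settings, among them the replicate block, also ended the call of the repressed genes, as listed in the section on processing. Induced genes missed it with library size alone and without a filter.

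The interaction count depended on the libraries: 11, 16 and 16 genes without untreated replicates 1, 2 and 3, 23 and 10 without ATRA replicates 1 and 3, 747 (414 higher, 333 lower) without DOX replicate 1, 129 and 21 without combined replicates 1 and 2, 9 without untreated replicate 3 and DOX replicate 3 together, and 117 with DESeq2. HLA-DQB1 and CD74 kept their call in each of these single omissions and without the pair, and PTAFR in the single omissions. At equal depth the calls of HLA-DQB1, HLA-DRA, PTAFR, S100A9, FGL2, CCR2, CHST2, WNT6, INAVA and BCL11A were lost, and without the pair those of HLA-DRA, PTAFR, BCL2, FGL2, CCR2, MS4A6A, CHST2, WNT6, INAVA and BCL11A. Library size alone ended those of HLA-DRA, S100A9, FGL2, CHST2, INAVA and BCL11A, the mitochondrial term those of CCR2, CHST2, INAVA and BCL11A, and removing length and GC trends that of BCL11A (0.45). Over all alternatives the change of CHST2 ranged from −1.35 to −1.02, that of INAVA from 0.64 to 0.86, CCR2 from −1.45 to −0.84, CD38 from −0.88 to −0.63 and BTG2 from −1.18 to −0.68, and that of CIITA never came nearer to 0 than −0.65. HLA-DQB1 ranged from −2.96 to −2.02, PTAFR from −1.90 to −1.31, FGL2 from −1.51 to −0.86 and MS4A6A from −1.34 to −0.85. BCL2 ranged from 0.68 to 1.10, WNT6 from 0.60 to 1.07 and BCL11A from 0.45 to 0.81. The calls of CIITA, CD38 and BTG2 were lost without any 1 untreated replicate, ATRA replicate 3 or combined replicate 2, without the pair, at equal depth and with library size alone. CIITA was also lost without ATRA replicate 1 or DOX replicate 2 and with the mitochondrial term, CD38 without ATRA replicate 2 or DOX replicate 3, and BTG2 without ATRA replicate 1 or 2 and with length and GC trends removed. HLA-DRA lost it without any 1 untreated replicate, ATRA replicate 1 or 3 or DOX replicate 2 (values −3.14 to −0.97 over all alternatives), S100A9 without any 1 untreated replicate or ATRA replicate 2 or 3 (1.67 to 2.24), and BCL2 without untreated replicate 1 or ATRA replicate 1 or 3. FGL2, CCR2 and MS4A6A lost it without untreated replicate 1 or 3 or ATRA replicate 3, the latter 2 also without DOX replicate 2 or combined replicate 2, and WNT6 without any 1 untreated replicate or ATRA replicate 3. CHST2, INAVA and BCL11A lost it without any 1 untreated or ATRA replicate, DOX replicate 2 or combined replicate 2, INAVA and BCL11A also without DOX replicate 3, and BCL11A without combined replicate 1.

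**Figure D4:**
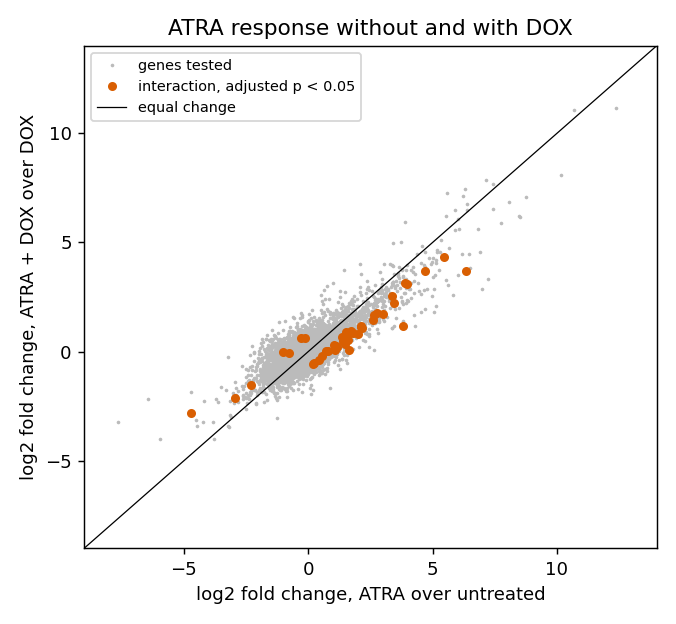
Log2 fold change under ATRA without DOX (x) and with DOX (y) for the 16104 genes tested; the 43 genes with an interaction are in orange and the line marks equal change. The slope of the relation over genes with a mean ATRA effect was 0.815, and 0.897 without DOX replicate 1.

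Averaged over both ATRA states, DOX lowered SLITRK5 by −1.77 ± 0.07, NRIP1 by −1.49 ± 0.09 and SYT2, a synaptotagmin gene, by −1.63 ± 0.23. It lowered ADAM28 by −1.38 ± 0.22, IGIP by −1.36 ± 0.23, ADAMTS14 by −1.37 ± 0.24, CLEC10A, a lectin gene, by −1.56 ± 0.50 and SCUBE3 by −1.24 ± 0.34. It raised GBP5 by 1.98 ± 0.25, CD52 by 1.82 ± 0.18, SLPI by 1.58 ± 0.20, TCF23 by 1.44 ± 0.21, IER3 by 1.42 ± 0.31, THBS1 by 1.39 ± 0.31, CCDC152 by 1.28 ± 0.13 and DUSP1, a stress-induced phosphatase gene, by 1.39 ± 0.47. DHRS9 rose by 1.13 ± 0.08, MPO by 0.91 ± 0.10 and CDKN1A by 0.63 ± 0.06. Of 3 measured fibroblast, endothelial and epithelial markers, PECAM1, KRT8 and KRT18, all 3 rose (3 over the list alone, median 0.43), 2 of them with DOX alone (3 over the list alone) and 2 with DOX in the presence of ATRA (2 over the list alone); with the mitochondrial ribosomal RNA term 1 was called in each of these 3. Nuclear respiratory chain genes rose at 25 and fell at 2 of 42 (29 and 2 over the list alone, camera adjusted p = 2.06e-09, adjusted p = 0.279 with an estimated correlation). Replication histone genes fell at 7 of 10 (7 over the list alone, adjusted p = 3.66e-05, adjusted p = 0.279 with an estimated correlation). Ribosome biogenesis genes rose at 9 of 30 (11 higher and 1 lower over the list alone, adjusted p = 0.00109, adjusted p = 0.301 with an estimated correlation). With the mitochondrial ribosomal RNA term the nuclear respiratory chain, histone and ribosome biogenesis lists were at adjusted p = 0.316, 0.123 and 0.297. Of 13 mitochondrially encoded genes edgeR called 8, and DESeq2 called 0 higher and 7 lower. Class II genes fell at 2 of 11 (2 over the list alone, median −0.55, camera adjusted p = 0.00291, adjusted p = 0.288 with an estimated correlation). By edgeR 3532 genes were called (1836 higher, 1696 lower), 274 by at least 1 on the log2 scale (58 higher, 216 lower). The count was 2218 without untreated replicate 3, 2279 without ATRA replicate 3, and 2252 without DOX replicate 2. It was 1719 at equal depth, 1668 without untreated replicate 3 and DOX replicate 3 together, and 326 with the term, which also ended the calls of ADAM28, IGIP, IER3, CLEC10A, SCUBE3 and DUSP1. CLEC10A was also not called without untreated replicate 1, ATRA replicate 3 or DOX replicate 2, SCUBE3 without untreated replicate 3, and DUSP1 without any 1 untreated or ATRA replicate, DOX replicate 2 or 3, or combined replicate 2 or 3. DUSP1 was also lost with DESeq2, with library size alone and with length and GC trends removed, CLEC10A at equal depth, and CLEC10A, SCUBE3 and DUSP1 without the pair. Over all alternatives ADAM28 ranged from −1.54 to −1.08, IGIP from −1.80 to −0.79, CLEC10A from −2.95 to −1.05 and SCUBE3 from −1.42 to −0.30. IER3 ranged from 0.79 to 1.76 and DUSP1 from 0.59 to 1.68.

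DOX effects measured without and with ATRA, which share no library, correlated across genes at Pearson r = 0.454 and Spearman rho = 0.478; genes are not independent replicates. Both comparisons called 153 genes higher, where 24.6 would overlap by chance, and 136 lower (29.1 by chance), against 4 in opposite directions (54.7 by chance). These chance values take all genes as equally likely to be called. The mitochondrial ribosomal RNA share was lower with DOX in both ATRA states, so library differences that go with that share could also give such an overlap. ATRA effects without and with DOX correlated at r = 0.826 and rho = 0.649, with 1372 genes higher in both (271 by chance), 878 lower in both (175) and 4 opposite (436). Without a filter on low counts these 2 Pearson correlations were 0.107 and 0.239. The mean ATRA and mean DOX effects correlated weakly across genes (r = 0.106, rho = 0.149), with 492 genes higher in both (352 by chance), 382 lower in both (296) and 648 opposite (646). That weak relation was 0.229 without combined replicate 1 and turned to −0.0150 without DOX replicate 1 and to −0.00517 with the mitochondrial ribosomal RNA term. Doxycycline and the shRNA came together in every library given DOX, so no effect here separates them.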

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

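The tests of sample differences, length and GC trends, shared reads and mitochondrial ribosomal RNA below were chosen after the results were seen; the interaction test and the alternatives of depth were planned.

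The test of the ATRA effect with against without DOX drew attention to 43 genes. Among the genes named by rule, HLA genes changed most, HLA-DRA by −2.67 and HLA-DQB1 by −2.63 on the log2 scale, followed among decreases by the platelet-activating factor receptor gene PTAFR (−1.57), FGL2 (−1.30), CHST2 (−1.22), CCR2 (−1.19), MS4A6A (−1.16) and CD74 (−1.15). HLA-DRA lost its call under 9 of 22 alternatives, with values from −3.14 to −0.97. S100A9 (1.91), the long noncoding RNA OLMALINC (0.99), WNT6 (0.93), BCL2 (0.82), INAVA (0.75), BCL11A (0.74) and the planar polarity gene VANGL1 (0.67) went the other way. VANGL1 lost its call without any 1 untreated replicate, ATRA replicate 1 or 3, combined replicate 2 or untreated replicate 3 and DOX replicate 3 together, and at equal depth, though its change stayed between 0.59 and 0.72. Of 100 splits that exchanged DOX labels within ATRA states, 6 gave 43 genes or more, the real one included. The other 5 (3532, 1273, 785, 146 and 58, with 3532 the highest other) kept the real groups in 1 ATRA state and exchanged 2 or 3 of 3 labels in the other. There the contrast takes up the mean DOX effect, a structure of the samples, so these splits do not decide whether chance can be excluded.

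Class II genes had a median difference of −1.81 between the ATRA effects. With length and GC trends removed the median was −1.78, and with mitochondrial ribosomal RNA as a term −2.12, which argues against either trend as the whole cause. Reads shared between HLA genes would spare CD74 and CIITA, which are not HLA genes, yet both passed the interaction test, with 0.0223 the larger adjusted p (edgeR quasi-likelihood). That covers CD74 and CIITA only, and leaves untested how shared reads shaped the HLA values and the list median. CD74 kept its call under all 22 alternatives, and CIITA lost it under 11 of 22, with a change that never came nearer to 0 than −0.65. An effect of lower RIP140 and one of doxycycline itself both stay open and untested, since no library separates them, and the list's adjusted p was 0.0629 with an estimated correlation.

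DOX called more genes without ATRA (2446) than with it (713), but the order turned to 77 against 597 with the mitochondrial ribosomal RNA term and to 169 against 627 without untreated replicate 3 and DOX replicate 3, and without DOX replicate 2 the former was 659. At 1 depth the ratio of both counts was 2.88, and with length and GC trends removed 2.19, so neither depth nor those trends alone account for the gap. Differences between libraries that go with mitochondrial ribosomal RNA stay open and cannot be told apart from DOX: with that term the 2446 genes kept 53.02% of their median log2 change (0.48 to 0.25), their median SE rose from 0.119 to 0.160, and 76 of them were still called, so calls ended both because changes shrank and because errors grew. The counts therefore do not show a larger effect of DOX without ATRA, and the interaction tested gene by gene passed for 43 genes. For 3 libraries against 3, the 10 splits are too few for a share under 0.05: 1 split, the real one, reached 2446 genes with 0 the highest other, and 1 reached 713 with 2 the highest other.

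Replication histone genes were lower and nuclear respiratory chain genes higher with DOX, and both may follow differences between libraries that go with mitochondrial ribosomal RNA. Within groups over 12 libraries, the histone mean correlated with it at r = 0.754 (exact permutation p = 0.0409 over 1296 arrangements; rho = 0.741, p = 0.0502; adjusted over 2 relations 0.0409 and 0.0502) and at 0.527 without untreated replicate 3 and DOX replicate 1. The respiratory chain mean correlated at r = −0.857 (exact permutation p = 0.00694, adjusted 0.0139; rho = −0.825, p = 0.0108, adjusted 0.0216) and at −0.830 without the same 2 libraries. Both values without these 2 libraries used deviations from group means that still included them, so they do not show how the relations hold without them. With the term, the median mean DOX effect went from −0.63 to −0.12 for histones and from 0.26 to 0.05 for the respiratory chain. Removing length and GC trends left histones at −0.63 but took the respiratory chain to 0.19, so a part by those trends stays open for the latter, and no biological explanation was separated from these. A difference in RNA selection, of which the histone list was written as a sign, was not tested either.

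Other lists passed camera with a preset correlation for a difference between the ATRA effects with and without DOX. The p53 targets had a median difference of −0.28 (adjusted p = 0.0058 with an estimated correlation), the one list that held under that test, while for the others it lay between 0.0629 and 0.624. Class I genes had −0.21, interferon genes −0.15, mature myeloid genes −0.29, azurophil granule genes −0.46, retinoid response genes −0.19, fatty acid oxidation genes −0.14, nuclear respiratory chain genes −0.25 and mitochondrially encoded genes −0.46. Cell cycle genes had 0.10, integrated stress genes 0.24, LXR and lipid genes 0.15, nuclear receptor coregulators and partner receptors 0.12 and replication histone genes 1.07. For histone, respiratory chain and azurophil granule genes, the DOX medians were −1.09, 0.39 and 0.51 without ATRA, against −0.17, 0.11 and −0.01 with it. Their differences thus came mostly from the DOX shift without ATRA, which for histone and respiratory chain genes shrank with the mitochondrial ribosomal RNA term. Mitochondrially encoded genes went the other way (−0.07 without and −0.48 with ATRA). The interferon list lost its call without untreated replicate 3, ATRA replicate 1 or 3, DOX replicate 1 or combined replicate 2 (adjusted p 0.0672 to 0.682). The LXR list lost it without untreated replicate 2, ATRA replicate 3, DOX replicate 1 or combined replicate 3 (0.0756 to 0.135), the cell cycle list without DOX replicate 1 (0.133) or combined replicate 3 (0.0636), and the retinoid list without DOX replicate 1 (0.0716). Over all ATRA-responsive genes the median difference signed by direction was −0.0971.

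Among the other comparisons of 3 against 3 libraries, the 10 splits were again too few for a share under 0.05: 1 split, the real one, reached 4652 genes for ATRA against untreated (0 the highest other), 3054 for combined against DOX (4 the highest other) and 6123 for combined against untreated (0 the highest other). For the mean DOX effect 1 of 100 splits, the real one, reached 3532 genes, with 1273 the highest other. That argues against chance labels only at that share, the smallest these splits can give. Exchanged labels cannot test differences between libraries that go with DOX, and the count was 326 with the mitochondrial ribosomal RNA term.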

How the results depend on the processing

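The mitochondrial ribosomal RNA term, the length and GC trends and the joint omission of untreated replicate 3 and DOX replicate 3 were chosen after seeing the data; the other alternatives were planned. Depth limited most counts: thinned to the total of the smallest library, ATRA called 2656 genes, DOX 1197, combined against ATRA 415, against DOX 1891, against untreated 3408, the interaction 15 and the mean DOX effect 1719, and NRIP1 under ATRA was −0.33 (adjusted p = 0.0855). Fewer reads gave fewer calls by construction; for the changes below the cause was not tested. Leaving out each library gave 3455 to 4006 genes for ATRA, 659 to 4326 for DOX (low without DOX replicate 2, high without DOX replicate 1), 264 to 907 for combined against ATRA (low without ATRA replicate 3). It gave 2195 to 3898 against DOX, 4392 to 5979 against untreated, 10 to 747 for the interaction (low without ATRA replicate 3, high without DOX replicate 1) and 2218 to 5141 for the mean DOX effect. NRIP1 ranged from −0.51 to −0.29 under ATRA and from 0.43 to 0.70 in the interaction, where it passed only without DOX replicate 1. The response size ranged from −0.122 to −0.0196 over all genes and from −0.104 to 0.0082 over repressed genes. The relation of the mean DOX and mean ATRA effects ranged from −0.0150 to 0.229. The interaction count was 24 with library size alone, 189 (77 higher, 112 lower) without a filter, 117 with DESeq2, 83 with length and GC trends removed and 9 without the pair of libraries. DOX gave 1573 genes with its groups fitted alone, 169 without the pair and 77 with the mitochondrial term, and the mean DOX effect 1668 and 326. Combined against untreated gave 3363 with the term, INSYN2B turned to 0.0163 under DOX and the mean effects' relation to −0.00517. By camera, the term turned the ribosome biogenesis list under DOX from adjusted p = 0.0412 upward to 0.527 downward. It turned the nuclear respiratory chain list in combined against ATRA from adjusted p = 0.00651 upward to 0.774 downward. With an estimated correlation these lists were at adjusted p = 0.592 and 0.632. The induced genes' response size missed the threshold with library size alone (−0.114) and without a filter (−0.150). That of repressed genes missed it at 10 CPM or more (−0.0418), with library size alone (−0.0806), without a filter (−0.0831), without the pair (−0.0493) and with the term (−0.0587). Deviations from group means over all genes showed no pairing by replicate number: 4 of 18 same-numbered pairs correlated above 0.1 (−0.244 to 0.267) and 3 libraries matched their own number best. Large differences between libraries can hide a pairing there, so a shared preparation is not excluded. With the replicate block the counts were 4677, 2349, 729, 3052, 6083, 54 and 3420 for ATRA, DOX, combined against ATRA, against DOX and against untreated, the interaction and the mean DOX effect. The block put the repressed genes' response size at −0.0737, past the threshold no longer. DESeq2 left 1562, 2186 and 2498 adjusted p missing for DOX, combined against ATRA and the interaction.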

Other observations

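The gene pairs and the sets of genes kept under several settings described here were chosen after the results were seen. SLITRK5 and MIR4500HG, a noncoding gene on the other strand of chromosome 13 whose start lies 1355 bp before that of SLITRK5 (positions 87427214 to 87671259), fell together: MIR4500HG by −2.21 ± 0.34 with DOX alone (edgeR quasi-likelihood adjusted p = 0.000843) and by −2.01 ± 0.35 with DOX in the presence of ATRA (adjusted p = 0.00143), against −1.70 ± 0.11 and −1.85 ± 0.10 for SLITRK5. SELENOP, the plasma selenoprotein gene, and CCDC152 overlap by 2481 bp on opposite strands of chromosome 5, and both rose: SELENOP by 1.29 ± 0.17 and 1.21 ± 0.13, CCDC152 by 1.44 ± 0.20 and 1.12 ± 0.16. Without strand, part of the overlap cannot be assigned to either gene. LCOR fell by −1.13 ± 0.12 averaged over both ATRA states, while NCOA7 rose by 0.39 ± 0.09. MIR4500HG and SELENOP fall outside the rule for named genes and were picked after their values were seen.

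Of the 3532 genes called for the mean DOX effect, 299 were also called with the mitochondrial ribosomal RNA term, 1636 without untreated replicate 3 and DOX replicate 3, and 2938 with library size alone; 276 were called in each of these (174 higher, 102 lower). Among these 276 were NRIP1, SLITRK5, DHRS9, CD52, CDKN1A, MPO and LCOR. Of 713 genes for combined against ATRA, 410 were called in each (170 higher, 240 lower), among them HLA-DRA, CD209, FGL2, PTGES, GBP5 and ADAM28. Of 2446 genes for DOX against untreated, 48 were called in each (39 higher, 9 lower). Of the 43 interaction genes 8 were: FAM43A, CD74, HLA-DQB1, HERPUD1, SAMHD1, TXNIP, OLMALINC and CD1D, the last a lipid antigen presenting molecule that ATRA raised by 4.69 ± 0.12 without and 3.72 ± 0.12 with DOX. FAM43A, HERPUD1, SAMHD1, TXNIP and CD1D were named after their values were seen.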
